A study of Homo sapiens with 6 samples.

How the data were processed

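RNA was measured in HEK293 cells treated with minocycline or with DMSO vehicle. Per the labels' protocols, total RNA was purified on silica columns with DNase digestion, libraries were made with a NEBNext Ultra II RNA kit, and paired-end reads were sequenced on an Illumina instrument. RNA selection, strandedness, the aligner, the counting program and the gene annotation were not given in the sources used here. Per the submitters' processing notes the genome build was hg19. The authors deposited a single table of whole-number counts per gene for all 6 libraries, with 57820 versioned Ensembl gene identifiers, and these counts carried no normalization. Replicates were not pooled, and each column named its library.

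Groups came from the treatment label, and 3 libraries per group are biological replicates according to the series' design text. Gene symbols came from a reference table of gene names, in which 55538 identifiers matched, and 98.7% of the counts fell in rows with a symbol. Gene positions, exon lengths and GC content were taken from a GENCODE annotation mapped to GRCh37, whose nuclear chromosomes have the coordinates of hg19. Exon length was the total over all annotated exons of a gene, which need not be the length of the transcripts present. The total count per library was 17303180 to 17835756. On simulated counts for 17225 genes, drawn from the means, dispersions and library sizes of these libraries with 200 genes changed, the test recovered 5.97% of the genes changed by 1.5-fold, 62.7% of those changed by 2-fold and 95.5% of those changed by 4-fold, and 2.68% of its calls were unchanged genes. The simulated genes varied independently and held no difference between libraries shared by many genes. These rates may therefore not hold for the measured counts. Pairs of libraries within a group differed by a chi-square per degree of freedom of 6.32 to 71.5, more than counting noise, and no library was a repeat of another.

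Genes were filtered with filterByExpr, libraries were scaled with TMM factors, and minocycline was tested against vehicle with edgeR 4.0.16 (glmQLFit and glmQLFTest at their default settings, R 4.3.3) in a model with treatment as its single term. Calls used a Benjamini-Hochberg adjusted p under 0.05. Values in CPM are TMM-scaled, and the standard error of a log2 fold change was its size divided by the square root of the F statistic. For the test of gene groups, 40 lists with 1095 members were fixed in advance, 1066 members matched a gene in the table, and the 37 lists with at least 5 measured members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were alternatives. The share of counts from mitochondrial genes was compared with a two-sided exact permutation test.

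The labels give each replicate number as the batch as well, so that same-numbered libraries share a batch, and the number was used as a block in an alternative fit. As a check, the deviations from the group means were correlated across genes between control and minocycline libraries, and same-numbered pairs gave -0.05, -0.29 and 0.30, while control replicate 1 and minocycline replicate 2 gave 0.50. Same-numbered libraries thus did not deviate together in every pair, and the pairing rests on the batch label.

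Genes named in the text followed a rule fixed before the data were examined. It took up to 10 rising and 10 falling genes with the largest change among those past the threshold, with a mean of at least 5 CPM and groups that did not overlap. It added the 4 members with the smallest adjusted p of each list past the camera threshold, a set of stress, lipid and iron genes with the mitochondrial mRNAs, and, where fewer than 10 passed in a direction, 5 genes with the next smallest unadjusted p. Genes named outside it are marked as such, and members of lists that it did not select are given as examples of their list.

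The alternatives set in advance were DESeq2-style (RLE), upper-quartile and library size scaling, DESeq2 1.42.0, limma-voom, no filter on low counts, at least 10 counts in every library, a minimum fold of 1.5, the replicate block, mitochondrial genes left out, and each library left out. After the data were seen, a correction for exon length and GC content by splines with 4 degrees of freedom per library, that correction with the block, 1 surrogate variable from sva 3.50.0, the newer quasi-likelihood method of edgeR, the block with an estimated correlation or fry, the correction and the surrogate variable each with an estimated correlation, and leaving out the chromosome 6 stretch with few counts were added.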

Results

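HEK293 cells, an established line derived from human embryonic kidney, were kept for 12 h with 100 µM minocycline or with its vehicle, dimethyl sulfoxide (DMSO), in the absence of heat shock. Minocycline is a tetracycline antibiotic, and drugs of this class bind bacterial and mitochondrial ribosomes. Gene counts were available for 6 total RNA libraries, 3 biological replicates of each group. The series places these libraries beside a polysome profiling experiment, and polysome fractions were not analysed here. The total count was 17821082, 17395826 and 17835756 in control replicates 1, 2 and 3, and 17830320, 17788105 and 17303180 in minocycline replicates 1, 2 and 3. The design holds a single comparison, minocycline against vehicle, which addresses how the abundance of transcripts in total RNA differed after the drug.

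The transcripts of 9 genes were higher with minocycline past the threshold. Of these, 7 were on a list of targets of the transcription factor ATF4 that was fixed in advance. STC2, which encodes the secreted glycoprotein stanniocalcin 2, rose from 44.7 ± 5.11 to 173 ± 18.7 normalised counts (CPM; mean ± SD, n = 3 per group). SLC7A11, the cystine and glutamate exchanger of the plasma membrane, rose from 12.8 ± 3.81 to 66.0 ± 3.54 CPM. ASNS, which makes asparagine, rose from 124 ± 17.5 to 372 ± 46.8 CPM, and PSAT1, an enzyme of serine synthesis, rose from 144 ± 12.4 to 354 ± 11.9 CPM. CHAC1, which degrades glutathione, rose from 11.8 ± 3.77 to 55.4 ± 5.64 CPM.

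Of 17225 genes tested with edgeR's quasi-likelihood test, 9 had a Benjamini-Hochberg adjusted p under 0.05, and all 9 were higher with minocycline. The log2 fold change was 1.96 ± 0.14 (SE) for STC2 (adjusted p = 0.00289), 2.37 ± 0.21 for SLC7A11 (adjusted p = 0.00649) and 1.88 ± 0.17 for FUT1, a fucosyltransferase (adjusted p = 0.00694). It was 1.30 ± 0.12 for PSAT1 (adjusted p = 0.00759), 1.59 ± 0.16 for ASNS (adjusted p = 0.00762) and 2.24 ± 0.24 for CHAC1 (adjusted p = 0.0127). DDIT4, an inhibitor of the kinase complex mTORC1, rose by 1.81 ± 0.21, and SLC6A9, a glycine transporter, rose by 2.34 ± 0.27 (adjusted p = 0.0208 for both). VEGFA, the vascular endothelial growth factor, rose by 1.01 ± 0.13 (adjusted p = 0.0488). VEGFA passed in 13 of 21 alternatives, and its call was lost with RLE factors, with library size scaling, with a minimum fold of 1.5 and with any library but control replicate 1 left out (adjusted p up to 1.00). The other 8 genes passed in 17 to 21. In each of these 9 genes the 3 minocycline libraries lay above the 3 control libraries, an arrangement in either direction that 9.31% of all genes tested showed and that chance gives in 10%. Within the 3 batches named in the labels, which hold 1 library of each group, the median log2 difference over the 9 genes was 1.95, 1.59 and 1.94, whose sign follows from the separated groups and is no further evidence. With minocycline replicate 1 or minocycline replicate 3 left out, 1 gene, STC2, passed, and without control replicate 2 the genes that passed were STC2, SLC7A11, FUT1 and CHAC1. Without control replicate 1, which lay beside 2 minocycline libraries on the first principal component, 3154 of 17658 genes passed, 1681 of them higher. The 9 genes were among them. Both remaining control libraries then lay above every minocycline library on that component, so that treatment ran along it. A call made in that setting alone, as reported for many genes below, is therefore weak evidence about the gene.

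**Figure D1:**
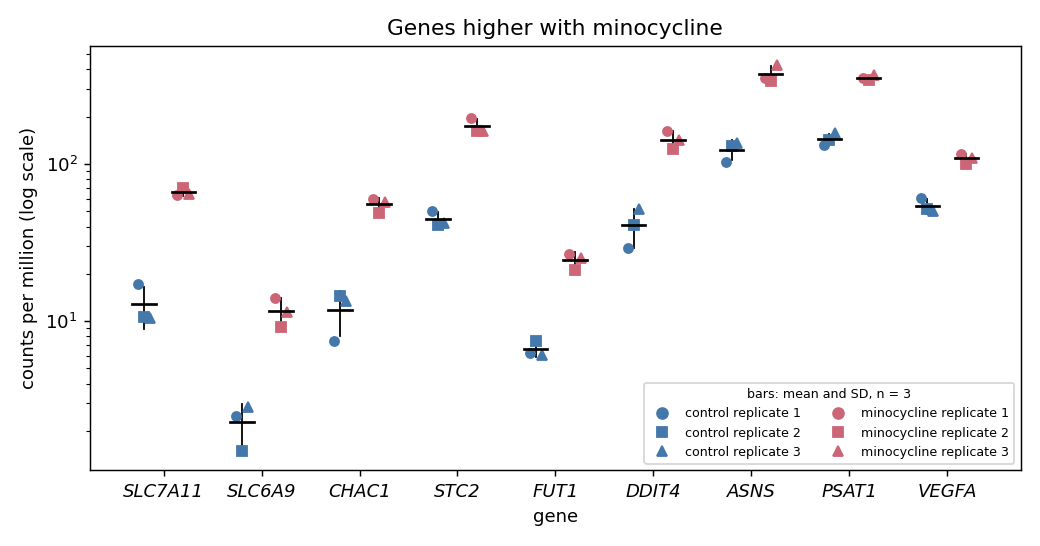
CPM, scaled for library composition, of the 9 genes that passed the test, on a log axis. Points are the 6 libraries, with symbols for the replicate number, and bars give the mean and SD of 3 libraries per group; STC2 went from 44.7 to 173 CPM and VEGFA from 54.1 to 109 CPM.

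In GRCh37 coordinates of the gene annotation, STC2 (ENSG00000113739.6) lies on chromosome 5 from 172741726 to 172755450 on the minus strand. SLC7A11 lies on chromosome 4 from 139085251 to 139163503, FUT1 on chromosome 19 from 49251268 to 49258647, and ASNS on chromosome 7 from 97480989 to 97501854, each on the minus strand. PSAT1 lies on chromosome 9 from 80912041 to 80945009, CHAC1 on chromosome 15 from 41245160 to 41248710, and DDIT4 on chromosome 10 from 74033678 to 74035794, each on the plus strand. SLC6A9 lies on chromosome 1 from 44457172 to 44497139 on the minus strand, and VEGFA on chromosome 6 from 43737921 to 43754224 on the plus strand. All 9 are annotated as protein-coding, and the counts are sums over each gene.

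A further 5 genes had the smallest unadjusted p among higher genes that did not pass, each at an adjusted p of 0.0523. They were GARS1 and MARS1, the glycyl- and methionyl-tRNA synthetases, the neutral amino acid transporter SLC1A4, the activin subunit gene INHBE and the alanine transaminase GPT2. Their log2 fold changes were 0.86 ± 0.12, 0.91 ± 0.12, 1.01 ± 0.14, 1.78 ± 0.25 and 0.93 ± 0.13. They passed in 8, 9, 8, 9 and 7 of 21 alternatives. INHBE had an adjusted p of 0.0258 with the replicate number as a block, within a range of 4.25e-11 to 0.469 over its 21 alternatives.

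No gene fell past the threshold in edgeR's test, where 340 genes were lower and 469 were higher at an unadjusted p under 0.05. DESeq2 gave 2 lower genes, IDI1 and MTCO3P12, and limma-voom gave 0. IDI1, an isomerase of the cholesterol pathway, went from 319 ± 15.4 to 200 ± 21.7 CPM, a log2 change of -0.67 ± 0.13 (adjusted p = 0.254). It ran from -0.76 to -0.59 over 21 alternatives and passed in 6, which were DESeq2, no filter on low counts, the length and GC correction with and without the block (adjusted p = 0.0384 without it), 1 surrogate variable (adjusted p = 0.00399) and the omission of control replicate 1, with an adjusted p of up to 1.00 in the others. MTCO3P12, a pseudogene copy of the mitochondrial gene MT-CO3 whose reads cannot be told from those of its parent with certainty, had a log2 change of -0.69 ± 0.15 (adjusted p = 0.465). The other 3 of the 5 lower genes with the smallest unadjusted p were VARS2, the ribosomal protein pseudogene RPL39P3 and the noncoding RNA gene LINC01619, and their adjusted p was 0.248, 0.820 and 0.820. MTCO3P12 and RPL39P3 passed in 4 and 3 of 21 alternatives, LINC01619 in 2 of 20 and VARS2 in 6 of 19. VARS2, the mitochondrial valyl-tRNA synthetase, had 82, 147 and 30 counts in the control libraries and 2, 14 and 2 with minocycline, a log2 change of -3.89 ± 0.74. With the replicate number as a block VARS2 passed (log2 change -4.01, adjusted p = 0.00177), where its adjusted p ran from 1.29e-21 to 0.935 over the 19 alternatives in which it was tested. Its level is uncertain, because it lies in a stretch of chromosome 6 where most genes had almost no counts, described among the closing observations.

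The targets of ATF4, the transcription factor of the integrated stress response, rose as a group. Of the 40 members of this list, all measured, 38 had a higher fitted level with minocycline, the median log2 fold change was 0.83, and camera gave an adjusted p of 1.73e-99 with a preset correlation and 0.0402 with an estimated correlation. With the replicate number as a block the estimated correlation gave an adjusted p of 0.276, and fry gave 0.0103 without the block and 0.207 with it. Over all genes tested 7 members passed (STC2, SLC7A11, PSAT1, ASNS, CHAC1, DDIT4 and SLC6A9), and adjusted over the list alone 31 passed, all of them higher. The median within batches 1, 2 and 3 was 1.18, 0.66 and 0.81. A list of amino acid starvation and mTORC1 regulators did not pass (23 measured, 10 higher and 13 lower, median -0.01, adjusted p = 0.296), with DDIT4 past the threshold over all genes. The regulator list passed with 1 surrogate variable (median -0.03, adjusted p = 0.000168, and 0.143 with an estimated correlation). Camera's direction in the main fit was higher although the median was below 0. The regulator list is not separate from the ATF4 list. Both hold DDIT4, SESN2 (0.83 ± 0.18) and EIF4EBP1 (0.60 ± 0.26), which had the smallest p among the regulators. The unshared regulators were not tested apart, and SESN2 and EIF4EBP1 were picked out after their values had been seen.

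ATF4 itself went from 691 ± 143 to 1163 ± 159 CPM, and its log2 fold change of 0.75 ± 0.19 did not pass over all genes (adjusted p = 0.810) and passed adjusted over the list alone (adjusted p = 0.00564). TRIB3, a pseudokinase gene induced by ATF4, showed 0.83 ± 0.22 (adjusted p = 0.820 over all genes and 0.00690 over the list alone). Over all genes both passed in the same 5 of 21 alternatives: no filter on low counts, the length and GC correction (adjusted p = 0.0242 for ATF4 and 0.0446 for TRIB3), that correction with the block, 1 surrogate variable, and the omission of control replicate 1. The log2 fold change ran from 0.59 to 0.98 for ATF4 (adjusted p from 4.11e-05 to 1.00) and from 0.61 to 1.15 for TRIB3 (adjusted p from 1.70e-05 to 1.00). Among the members that passed neither adjustment, DDIT3, which encodes CHOP, showed 0.41 ± 0.30, PPP1R15A, which encodes GADD34, showed -0.22 ± 0.17, ATF3 showed 0.13 ± 0.12, and the stress cytokine gene GDF15 showed 0.29 ± 0.37. ATF5 showed -0.35 ± 0.15, with 0.0580 over the list alone. The log2 fold change of DDIT3 ran from 0.15 to 0.88 over its 21 alternatives, and it passed with 1 surrogate variable (adjusted p = 0.00568, range 0.00568 to 1.00). PPP1R15A and ATF5 passed as lower genes without control replicate 1 (adjusted p = 0.0266 and 0.0168) and in no other alternative, and ATF3 and GDF15 passed in none. DDIT3 overlaps the end of MARS1 on the opposite strand of chromosome 12, and strand use in the counting was not given in the sources used here, so the levels of both are uncertain. PPP1R15A, ATF3, GDF15 and ATF5 were picked out after their values had been seen.

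The cytosolic aminoacyl-tRNA synthetases, which charge transfer RNAs with amino acids, also rose as a group. Of 19 measured members 14 had a higher fitted level, the median log2 fold change was 0.47, and the camera adjusted p was 1.81e-15 with the preset and 0.0402 with an estimated correlation. No member passed over all genes, and 12 passed adjusted over the list alone, all higher. These included GARS1, MARS1, CARS1 (0.82 ± 0.13) and YARS1 (0.67 ± 0.13). HARS1, KARS1 and RARS1 had log2 fold changes of -0.13 ± 0.12, -0.07 ± 0.13 and -0.01 ± 0.12 and passed neither adjustment; they too were picked out after their values had been seen. Over all genes CARS1 and YARS1 passed in 6 and 4 of 21 alternatives (adjusted p from 2.55e-05 and 0.000231 to 1.00), and HARS1, KARS1 and RARS1 in none. The median within batches 1, 2 and 3 was 0.18, 0.53 and 0.40, and with the replicate block the estimated correlation gave an adjusted p of 0.276. Fry gave an adjusted p of 0.00524 without the block and 0.0490 with it. With the length and GC correction, chosen after the data were seen, the estimated correlation gave 0.221 for this list and 0.0130 for the ATF4 targets, and GARS1 had an adjusted p of 0.534 (range 2.26e-08 to 1.00 over its 21 alternatives). The median of the synthetase list was then 0.41, with a camera adjusted p of 7.39e-13 at the preset correlation. The log2 fold change of GARS1 ran from 0.65 to 0.93 over its alternatives. The 17 measured mitochondrial synthetases had a median of 0.00 and did not pass (adjusted p = 0.447), and the difference between the 2 lists was not tested.

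The enzymes of serine, glycine and folate metabolism passed as a higher group with the preset correlation (19 measured, median log2 fold change 0.12, adjusted p = 2.03e-05) and not with an estimated correlation (adjusted p = 0.384). PSAT1 passed over all genes, and 6 members passed adjusted over the list alone, including MTHFD2 (0.77 ± 0.12), MTHFD1L (0.62 ± 0.14) and PSPH (0.65 ± 0.15). Over all genes these 3 passed in 5, 3 and 4 of 21 alternatives. The ATF4 list shares 6 of these genes. The 13 unshared members had a median of -0.11, and camera with the preset correlation gave p = 0.832 for them. The medians within the batches were 0.31, 0.10 and -0.11. The call for the list was lost without control replicate 1 (adjusted p = 0.0695), and its median was 0.07, 0.01, 0.07, 0.05 and 0.22 without control replicates 2 and 3 and minocycline replicates 1, 2 and 3.

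The chaperones and unfolded protein response genes of the endoplasmic reticulum passed with the preset correlation (36 measured, median 0.19, adjusted p = 0.000295) and not with an estimated correlation (adjusted p = 0.593). In the main fit no member passed under either adjustment. XBP1 had the smallest p of the list at 0.55 ± 0.13, ATF6 showed 0.44 ± 0.17, HERPUD1 0.44 ± 0.18, SDF2L1 -0.31 ± 0.13 and the chaperone gene HSPA5 0.28 ± 0.23. HSPA5 ran from 0.04 to 0.62 over its 21 alternatives and passed without control replicate 1 (adjusted p = 0.00669, range 0.00669 to 1.00). Over all genes XBP1 passed with 1 surrogate variable (adjusted p = 0.00117) and without control replicate 1, HERPUD1 with 1 surrogate variable (adjusted p = 0.0108) and ATF6 without control replicate 1 (adjusted p = 0.0104), each in no other alternative, and SDF2L1 in none. The medians within the batches were -0.04, 0.31 and 0.35, and the median was 0.30 without control replicate 1 and 0.10 without control replicate 3.

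**Figure D2:**
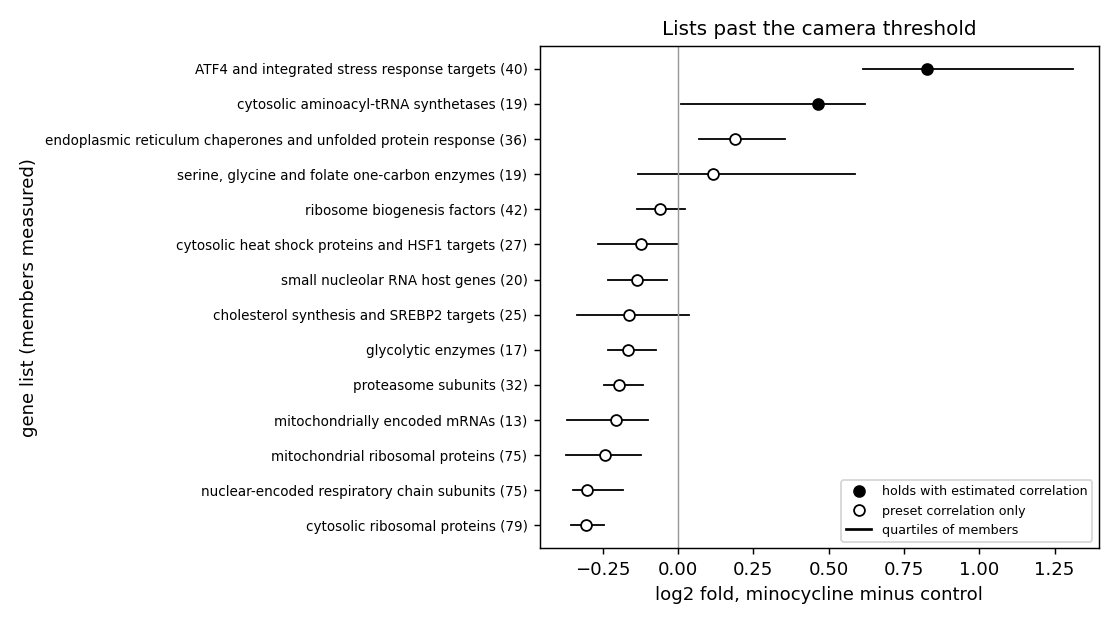
Median log2 fold change, minocycline minus control, of the members of the 14 lists past the camera threshold, with lines from the lower to the upper quartile. Filled circles mark the 2 lists whose call held with an estimated correlation, with medians of 0.83 and 0.47.

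Among the 10 lists that passed in the lower direction with the preset correlation, the strongest calls were for transcripts of abundant protein complexes. Of 79 cytosolic ribosomal protein genes 78 had a lower fitted level (median log2 change -0.30, adjusted p = 1.79e-12), of 75 nuclear-encoded respiratory chain subunits 71 had one (median -0.30, adjusted p = 2.04e-12), and of 75 mitochondrial ribosomal proteins 70 had one (median -0.24, adjusted p = 4.25e-12). All 32 measured proteasome subunits had a lower fitted level (median -0.19, adjusted p = 2.88e-06). The estimated correlation between members was 0.89, 0.77, 0.59 and 0.38 in these 4 lists, against the preset 0.01. Their members are thus not independent, and the counts of lower members and the preset p overstate the evidence. With an estimated correlation each of these 4 lists had an adjusted p of 0.593, and no member passed over all genes or adjusted over its list alone. The members named by the rule included RPS10 (-0.36 ± 0.15) and RPL17 (-0.33 ± 0.14), NDUFB2 (-0.42 ± 0.17) and ATP5MC1 (-0.41 ± 0.17), MRPL34 (-0.53 ± 0.20) and MRPL12 (-0.51 ± 0.20), and PSMA3 (-0.32 ± 0.14) and PSMD3 (-0.34 ± 0.15). RPS10 and RPL17 had means of 14.5 and 24.2 CPM, against a median of 970 CPM for the ribosomal protein list, and are not typical of it. Of these, MRPL34, MRPL12, NDUFB2, ATP5MC1 and PSMD3 passed over all genes without control replicate 1 (adjusted p between 0.00469 and 0.0137) and in no other alternative, and RPS10, RPL17 and PSMA3 in none.

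These 4 lists moved with a gradient between libraries that crossed the groups. Ribosomal protein genes took 7.52%, 11.2% and 12.5% of the counts in control replicates 1, 2 and 3, and 8.51%, 7.48% and 11.01% in minocycline replicates 1, 2 and 3. The 95% Wilson intervals of these shares were at most 0.0307 points wide and cover counting error only. The first principal component held 52.9% of the variance and set control replicate 1 (-34.9), minocycline replicate 2 (-32.3) and minocycline replicate 1 (-14.0) apart from minocycline replicate 3 (3.06), control replicate 2 (31.1) and control replicate 3 (47.1). Within batches 1, 2 and 3 the ribosomal protein median was 0.12, -0.69 and -0.29, and that of the respiratory chain was 0.04, -0.53 and -0.32. The mitochondrial ribosomal median was 0.0001, -0.42 and -0.31, and the proteasome median was -0.05, -0.30 and -0.26. Without control replicate 1 the medians of the cytosolic ribosomal, respiratory chain, mitochondrial ribosomal and proteasome lists were -0.51, -0.45, -0.42 and -0.33, and without control replicate 3 they were -0.14, -0.15, -0.15 and -0.12, past the preset threshold in both cases. The ribosomal protein median was also -0.19 without minocycline replicate 2 and -0.53 without minocycline replicate 3. With 1 surrogate variable in the model the ribosomal protein median was 0.02 (adjusted p = 0.704, range 8.22e-26 to 0.9498 over its alternatives) and the respiratory chain median was -0.02 (adjusted p = 0.116, range 2.65e-20 to 0.879). The mitochondrial ribosomal and proteasome lists kept their preset call there, each with a median of -0.08 (adjusted p = 0.000786 and 0.00273, and 0.704 for both with an estimated correlation).

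**Figure D3:**
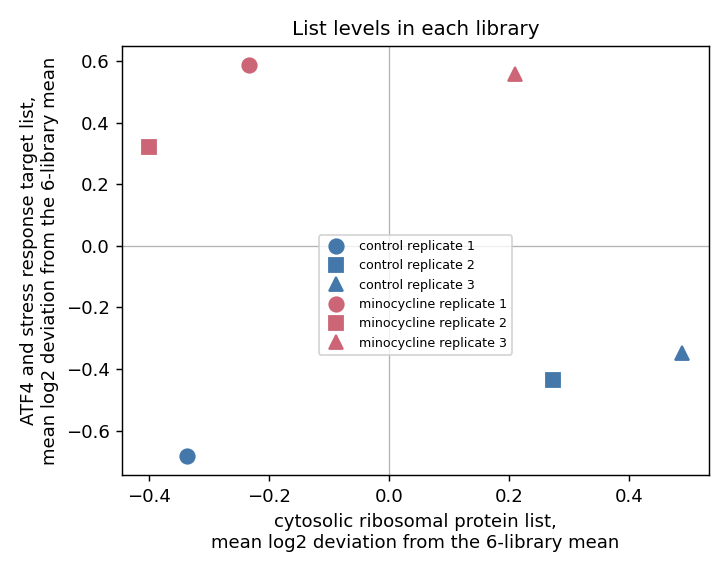
Mean log2 level of the members of 2 lists in each library, as the deviation from the mean of the 6 libraries; the horizontal axis is the cytosolic ribosomal protein list and the vertical axis the ATF4 target list. The ATF4 list lay between 0.32 and 0.59 in the minocycline libraries and between -0.68 and -0.35 in the control libraries, whereas the ribosomal protein list was at -0.34 in control replicate 1 and at 0.21 in minocycline replicate 3.

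Genes of cholesterol synthesis were lower as a group with camera (25 measured, 17 lower, median log2 change -0.16, adjusted p = 0.000195) and with fry (adjusted p = 0.00524). The adjusted p was 0.127 with an estimated correlation. IDI1 passed adjusted over the list alone (adjusted p = 0.0128). MVD showed -0.59 ± 0.16, ACAT2 -0.42 ± 0.14, FDFT1 -0.43 ± 0.15 and HMGCS1 -0.27 ± 0.17, of which HMGCS1 passed with 1 surrogate variable (adjusted p = 0.0367, range 0.0367 to 1.00 over 21 alternatives). MVD, ACAT2 and FDFT1 passed over all genes without control replicate 1 (adjusted p = 0.00161, 0.00862 and 0.00479) and in no other alternative. That setting called 3154 of 17658 genes. The medians within batches were -0.20, -0.10 and -0.11, and without minocycline replicate 2 the median was -0.09. With the replicate block fry gave an adjusted p of 0.212.

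The heat shock proteins and HSF1 targets were lower with the preset correlation (27 measured, median -0.12, adjusted p = 0.00401) and not with an estimated correlation (adjusted p = 0.384). Their members went both ways, with DNAJB1 at -0.28 ± 0.12, AHSA1 at -0.35 ± 0.13 and SERPINH1, a collagen chaperone gene, at 0.42 ± 0.13, and none passed under either adjustment in the main fit. SERPINH1 and AHSA1 passed over all genes without control replicate 1 (adjusted p = 0.00888 and 0.0130), HSPA1B in 2 of 20 alternatives and DNAJB1 in none. The call was lost without control replicate 1 (adjusted p = 0.0951) or minocycline replicate 1 (median -0.08, adjusted p = 0.103), and the median was -0.18 without minocycline replicate 2. Within batches 1, 2 and 3 the median was -0.14, -0.05 and -0.22. HSPA1A was not tested after the filter on low counts, with 5, 9 and 18 counts in the control libraries and 4, 7 and 89 with minocycline, and HSPA1B showed -1.0 ± 0.35; both are near-identical copies in the chromosome 6 stretch with few counts, and their levels are uncertain.

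Glycolytic enzymes (median -0.17, adjusted p = 0.00200), small nucleolar RNA host genes (median -0.14, adjusted p = 0.0118) and ribosome biogenesis factors (median -0.06, adjusted p = 0.0442) were also lower with the preset correlation. Their adjusted p was 0.593, 0.685 and 0.593 with an estimated correlation, and that of the biogenesis factors was 0.0672 with the replicate block, within a range of 4.56e-06 to 0.676 over its alternatives. The lowest unadjusted p in each was that of PGAM1 (-0.37 ± 0.14), SNHG9 (-0.61 ± 0.23) and NOP16 (-0.37 ± 0.14), and no member passed under either adjustment in the main fit. These 3 passed over all genes without control replicate 1 (adjusted p = 0.0317, 0.0156 and 0.0290) and in no other alternative. The median of the biogenesis factors was 0.01 when libraries were scaled by their size alone. Within batches 1, 2 and 3 the glycolytic median was 0.07, -0.10 and -0.39. That of the host genes was 0.09, -0.31 and -0.15, and that of the biogenesis factors -0.17, 0.07 and -0.10, so each changed sign between batches. The glycolytic call was lost without control replicate 3 (median -0.08, adjusted p = 0.0655) and with 1 surrogate variable (median -0.07, adjusted p = 0.0540), as was that of the host genes with the surrogate variable (median 0.06, adjusted p = 0.706). That of the host genes was lost without control replicate 3, minocycline replicate 1 or minocycline replicate 2 (adjusted p = 0.333, 0.0706 and 0.303), with a median between -0.06 and -0.29 over the omissions. That of the biogenesis factors was lost without control replicate 1, minocycline replicate 1 or minocycline replicate 3 (adjusted p = 0.566, 0.344 and 0.181), with medians of -0.012, -0.0027 and -0.09, and the median was -0.11 without minocycline replicate 2.

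Transcripts of the mitochondrial genome were compared because tetracyclines also bind the mitochondrial ribosome. Counts from mitochondrial genes made up 1.28% ± 0.140 of the total in the control libraries and 1.20% ± 0.0373 in the minocycline libraries (SD, n = 3 each), a difference of -0.0846 percentage points that was smaller than the spread of the controls (two-sided exact permutation p = 0.6, where 3 against 3 cannot go below 0.1). The difference was -0.142 points without control replicate 1 (exact permutation p = 0.1, the smallest that 2 against 3 can give) and -0.00651 points without control replicate 2 (exact permutation p = 0.9). Within batches 1, 2 and 3 the share was 1.17%, 1.44% and 1.24% in the control and 1.19%, 1.17% and 1.24% in the minocycline library, with 95% Wilson intervals at most 0.0112 points wide.

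The 13 mitochondrially encoded mRNAs passed camera as a lower group with the preset correlation (median log2 change -0.21, adjusted p = 0.0481) and not with an estimated correlation (adjusted p = 0.593), and no member passed under either adjustment. MT-ND4 went from 1262 ± 451 to 740 ± 57.1 CPM (-0.77 ± 0.25) and the overlapping MT-ND4L showed -0.85 ± 0.27, lower with minocycline in 3 of 3 batches, as were MT-ND1, MT-ND6 and MT-ATP6. MT-ND5 (0.45 ± 0.19), MT-ATP8 (0.63 ± 0.27) and MT-CYB (0.22 ± 0.14) had higher fitted levels, each in 3 of 3 batches. The other 8 lay between -0.40 ± 0.16 for MT-ND6 and -0.10 ± 0.19 for MT-ND3, with MT-CO1 at -0.12 ± 0.16, MT-CO2 at -0.11 ± 0.20, MT-CO3 at -0.21 ± 0.19, MT-ND1 at -0.23 ± 0.17, MT-ND2 at -0.34 ± 0.22 and MT-ATP6 at -0.37 ± 0.17. The same sign in 3 batches is weak evidence, because chance often gives it. For MT-ATP8, MT-CYB and MT-ATP6 it follows from groups that did not overlap, whereas the groups of MT-ND4 and MT-ND4L overlapped. MT-ND1 differed little in batch 1 (641 CPM in the control and 631 CPM in the minocycline library). Over 20 alternatives MT-ND4 ran from -1.01 to -0.48 and MT-ND4L from -1.10 to -0.52, and both passed with no filter on low counts and without control replicate 1 (lowest adjusted p 0.000779 and 0.000195, highest 1.00). Without control replicate 1, where 3154 of 17658 genes passed, MT-ND2, MT-ND5, MT-ND6, MT-ATP6 and MT-ATP8 passed too (adjusted p = 0.0123, 0.00910, 0.00665, 0.0212 and 0.0217, and up to 1.00 over the alternatives). The mitochondrial ribosomal RNAs MT-RNR1 and MT-RNR2 showed -0.16 ± 0.19 and -0.13 ± 0.18. The median of the mRNAs was 0.01, -0.54 and -0.14 within the 3 batches. The list's call was lost without control replicate 2 (median -0.07, adjusted p = 0.495), minocycline replicate 1 (adjusted p = 0.160) or minocycline replicate 3 (adjusted p = 0.177), and its median was -0.34 without control replicate 1. It was also lost with the length and GC correction (median -0.13, adjusted p = 0.201), with that correction and the block (median -0.13) and with 1 surrogate variable (median -0.09, adjusted p = 0.325).

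Genes for other responses fixed in advance did not pass in the main fit. TFRC, the transferrin receptor, showed -0.05 ± 0.33, the heme oxygenase gene HMOX1 -0.01 ± 0.24 and the cell cycle inhibitor gene CDKN1A -0.29 ± 0.21. Over 21 alternatives these ran from -0.40 to 0.48, from -0.27 to 0.38 and from -0.51 to 0.04. TFRC and CDKN1A passed without control replicate 1 (adjusted p = 0.0479 and 0.0116, and up to 1.00 in the others), and HMOX1 passed in none (lowest adjusted p 0.146). Markers of other cell types did not pass as lists: the fibroblast list had an adjusted p of 0.765 (7 measured) and the neuronal list 0.447 (9 measured), while 2 blood cell markers and 4 keratinocyte or cervical carcinoma markers were measured, too few for the test. COL1A1 was at 77.2 ± 4.19 CPM in the control libraries, KRT17 at 102 ± 12.2 CPM and NEFM at 79.7 ± 8.35 CPM.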

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

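The 9 genes kept a higher fitted level with minocycline under all 21 alternatives, and STC2 passed under each of them. The length and GC corrections, the surrogate variable, the newer quasi-likelihood method, the omission of the chromosome 6 stretch and the joint settings of block, correction or surrogate variable with an estimated correlation or fry were chosen after seeing the data. Against 9 genes changed, 9 higher and 0 lower, DESeq2 gave 50, with 48 higher and 2 lower, no filter on low counts gave 94, with 75 and 19, and a minimum fold of 1.5 gave 3, all higher. The length and GC correction gave 29 (28 higher and 1 lower), the same with the replicate block 35 (33 and 2), and the surrogate variable 90 (82 and 8). All 9 genes were among the calls under each of these except the minimum fold, where SLC7A11, STC2 and FUT1 passed. The replicate block gave 13 genes, 12 higher (with INHBE beside the 9, and PCK2 and SLC7A5, which lie outside the naming rule and were named after their values were seen) and 1 lower (VARS2), and apart from the calls given beside the results it changed no other call among the genes and lists named above. The other settings of scaling, tool, filter and gene set gave 8 to 13 genes, none lower. With each library left out in turn the count ran from 1 to 3154, with 1 to 1681 higher and 0 to 1473 lower. The number of lists was 14 against 2 with an estimated correlation, 3 with fry, and 0 with the replicate block and an estimated correlation. It was 1 (the cytosolic aminoacyl-tRNA synthetases) with the block and fry, and 1 (the ATF4 list) with the length and GC correction and an estimated correlation. It was 2 with the surrogate variable and an estimated correlation, and 11 to 15 with a library left out. With the surrogate variable the median of the ribosomal protein list turned to 0.0197 and that of the small nucleolar RNA host genes to 0.0576, and TFRC ran from -0.288 to 0.485 with a library left out, the latter without control replicate 1 (adjusted p = 0.0479, range 0.0479 to 1.00 over its alternatives). The cause was not tested, except that fewer libraries were fitted where a library was left out and that the minimum fold and the filter changed the test or the genes tested by construction. Fewer libraries alone do not account for the 3154 genes without control replicate 1. There the remaining controls (31.1 and 47.1 on the first principal component) lay apart from the minocycline libraries (-14.0, -32.3 and 3.06). Treatment and the gradient between libraries cannot be told apart in that fit. The mitochondrial share differed by -0.142 to -0.00651 points with a library left out. In the simulation, which held no gradient shared by many genes, a change of 1.5-fold was recovered for 5.97% of genes. Smaller changes were thus mostly not detectable in such counts, and the rate for the measured counts is not known.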

Other observations

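Several lists did not pass camera in the model with treatment alone and the preset correlation. The mitochondrial chaperones and proteases had a median log2 fold change of 0.01 over 22 measured genes (adjusted p = 0.252), the NRF2 targets -0.16 over 24 (adjusted p = 0.874, camera's direction higher), the p53 targets -0.10 over 26 (adjusted p = 0.361) and the interferon-stimulated genes -0.07 over 22 (adjusted p = 0.293). SLC7A11, which belongs to the NRF2 list as well as to the ATF4 list, was the member of the NRF2 list that passed over all genes, and VEGFA was the member of the hypoxia list that did so (27 measured, median 0.02, adjusted p = 0.293). Genes of DNA replication (median -0.06, adjusted p = 0.293) and of mitosis (median -0.04, adjusted p = 0.252) did not pass. The mitochondrial chaperones passed with the length and GC correction (median -0.09, adjusted p = 0.0174), and with 1 surrogate variable the NRF2 targets (median -0.01, adjusted p = 0.0114) and the mitosis genes (median -0.08, adjusted p = 0.00957) passed; their adjusted p was 0.5996, 0.299 and 0.704 there with an estimated correlation. With another scaling the medians of 4 of these lists changed sign, to -0.01 with RLE factors for the mitochondrial chaperones and, with library size alone, to 0.00, 0.02 and 0.02 for the interferon, replication and mitosis lists. NEAT1, a nuclear noncoding RNA, went from 240 ± 79.4 to 387 ± 5.13 CPM, with a log2 fold change of 0.69 ± 0.21 that passed adjusted over its list alone (adjusted p = 0.0460) and not over all genes (adjusted p = 0.820); it was picked out after its values had been seen, and passed over all genes in 3 of 21 alternatives (adjusted p from 0.000330 to 1.00).

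All tests in the next 3 paragraphs were chosen after the result was seen. The rise of the ATF4 list was set against technical explanations. Trends of exon length and GC content between libraries predicted a loss of the rise once removed, and the median log2 fold change was 0.836 afterwards against 0.826 before. This covers annotated exon length, not the length of the transcripts present. The main gradient between libraries predicted the same, and with a surrogate variable estimated on genes outside all lists the median was 0.978 (adjusted p = 0.0380 with an estimated correlation), while a single deviating library is argued against by the gap of 0.668 between the lowest minocycline and the highest control library in the mean log2 level of the list. Of the 10 splits of the 6 libraries into groups of 3, 1 gave a median as large (0.826, against 0.516 at most in the others), 1 gave as many lists (14 against at most 10) and 2 gave as many genes (9 against up to 2824), and so few splits cannot give a share under 0.05. The list and its main tests were fixed in advance, whereas these checks were not. With the replicate block the median was 0.848, and the call held at the preset correlation (camera adjusted p = 5.32e-98). It was lost there with an estimated correlation (camera adjusted p = 0.276) and with fry (adjusted p = 0.207). That minocycline may raise the ATF4 targets therefore stays a hypothesis. Among the 4 splits that part every pair of same-numbered libraries the others gave 0 genes, up to 10 lists and a median of at most 0.450. Each of those others mixes treated and control libraries on both sides. A drug effect would then widen the spread within a side and lower the count of genes, so the contrast cannot decide.

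The lower level of the ribosomal protein, respiratory chain, mitochondrial ribosome and proteasome lists was set against the same gradient. The split of control replicate 1, minocycline replicate 1 and minocycline replicate 2 from the rest called 2824 genes. These are the libraries with negative scores on the first component, so this count restates the gradient and is no separate evidence for it. With the surrogate variable estimated outside all lists the median over the 261 members was -0.0204 (quartiles -0.10 and 0.03), against -0.278 (quartiles -0.34 and -0.18) without it. Most of this difference thus lay along the gradient. The gradient was partly aligned with treatment, since the log2 fold change followed the loadings of the first component across genes (Pearson r = -0.766). The surrogate variable can therefore remove a drug effect too, and cannot tell it from the gradient. Annotated exon length and GC content alone are argued against as the whole cause, since the median was -0.241 after their trends were removed. Exon length was the total over all annotated exons, with a median of 3228 for the ribosomal protein list and 4742 for all genes tested. A trend on the length of the transcripts present is thus not excluded. The loadings of the first component followed exon length across genes (Spearman rho = -0.485), where genes are not independent replicates. An effect of minocycline on these lists stays open. The mitochondrial ribosome and proteasome lists had medians of -0.08 for both in the model with 1 surrogate variable.

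Most genes in a stretch of chromosome 6 that holds the major histocompatibility complex, between 28471073 and 33425321 in GRCh37, had almost no counts: of its 178 protein-coding genes 84.3% had a mean under 1 CPM, against 30.0% of the 810 others on the chromosome, and the tubulin gene TUBB had 0 counts. The absence of the stretch from these cells is argued against by PRRC2A, HLA-C and BRD2, which lie inside it and had means of 99.8, 118 and 64.7 CPM. In 7 lists searched, 7 members from 5 lists lie in the stretch and ranked at a median percentile of 1.27 within their own lists; 3 of them (HSPA1L, HSPA1A and HSPA1B) are heat shock genes, which can be low without heat shock, and the other 4 (RPS18, MRPS18B, VARS1 and VARS2) had a median of 0.633. A candidate explanation is that reads were lost in the authors' alignment or counting, for instance where a genome file also holds alternate copies of this region. The lower counts of VARS2 with minocycline may then reflect the few reads kept there, which these tables cannot settle.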
